A study of Mus musculus with 20 samples.

How the data were processed

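RNA abundance was measured by bulk sequencing of polyA RNA from endothelial cells sorted out of adult mouse sciatic nerve. In the Tomato experiment, Cdh5(PAC)-CreERT2 switched on a red reporter at the Rosa26 locus. Cells came from pooled uninjured nerves (intact, 5 libraries) or from the bridge, the tissue that forms at the lesion, at 7 days (7 dpi, 5 libraries) or 14 days (14 dpi, 4 libraries) after injury. In the Cherry experiment, cells carried a Kdr-Cherry reporter and came from the bridge at 7 dpi of control mice (WT, 3 libraries) or of mice with endothelial deletion of Plxnd1 (KO, 3 libraries). Per the labels' protocols, nerves were pooled, dissociated with enzymes at 37 C for 30 min and sorted as reporter-positive, CD45-negative cells. The design text calls the injured tissue a bridge and the condition label calls the injury a crush, and which applied is not settled by the sources used here. The labels give each library a batch, 1133 or 1292, and both batches hold every group. No label says which animals or nerves a library came from, so p-values measure the spread between libraries, which may in part be technical.

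The deposited values are raw counts per gene in whole numbers, per the file headers, 1 table for each experiment and 1 further table of Cherry counts that the authors corrected for batch with ComBat-Seq. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.5.3a and featureCounts 1.6.4 with genome build mm10 (GRCm38). Cell Ranger 3.0.2 is also named there, although these are bulk libraries. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Overlapping genes, antisense partners and near-identical copies (Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, the Ifit and Oas families, the MHC genes) may share reads. Of 55376 genes in the tables, 54510 symbols were found in the GENCODE M21 annotation and 48692 of those (89.3%) had the same chromosome, start and end; coordinates are those of the deposited tables. All sample columns of the tables were mapped to a library. Running ComBat_seq with genotype as the protected variable gave the same whole number as the authors' corrected table in 90.3% of values of genes with any count, against 56.9% without genotype.

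Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, and the robust quasi-likelihood F test, with batch in every model. The 14 Tomato libraries shared 1 fit for the comparisons of 7 dpi with intact, 14 dpi with intact and 14 dpi with 7 dpi, and the 6 Cherry libraries had their own. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are log2. The standard error (SE) given with them is an approximation, the absolute log2 fold change divided by the square root of its F value. CPM values are TMM-scaled within an experiment; the experiments were normalized separately, and levels set side by side across them are descriptions. Plxnd1 was also compared with two-sided exact permutation tests of log2 CPM. The replicate libraries of a group were not duplicates: over 32 pairs, the chi-square per degree of freedom of their counts was 18.2 to 149.2.

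The design of each test, 36 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. The p-values were adjusted over the 36 lists of a comparison. The lists were pan-endothelial identity, tip cell and sprouting, Notch, S phase, G2 and mitosis, barrier, Wnt, matrix, proteases, arterial, venous, capillary lipid uptake and lymphatic. Further lists were hypoxia and glycolysis, oxidative phosphorylation, VEGF and angiopoietin, semaphorin family, other axon guidance, flow, YAP and TAZ, TGF-beta and BMP, mesenchymal transition, angiocrine, leukocyte adhesion, antigen presentation, interferon, immediate early and unfolded protein response. There were 8 lists of other cells (fibroblast, perineurial, mural, Schwann, macrophage, other leukocyte, erythrocyte, muscle and fat). The naming rule took, per comparison, up to 6 rises and 6 falls of the greatest fold among called genes with an average log2 CPM of at least 3, 1 sign in both batches and a symbol that is not a bare gene model. It added up to 2 rising and 2 falling called members and the first 2 symbols of each list, Plxnd1, Kdr, Cdh5 and Pecam1; and semaphorin family members that passed over the list alone in the KO comparison. If fewer than 12 genes had passed, the 10 with the smallest p would have been given as values. The text names part of the genes this rule allows, a selection made after their values were seen. Tmcc1 and Timp4 in the KO comparison and the genes of a chromosome 10 window lie outside it and were also chosen after their values were seen.

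The alternatives were DESeq2 1.42.0, limma voom for the KO comparison, RLE factors or library size in place of TMM, no low-count filter, and at least 10 counts in every library of a group. Others were no batch term, each batch alone, the compared groups alone, each library left out in turn, blocks of libraries with neighbouring title numbers, and the authors' ComBat-Seq counts (sva 3.50.0 for the corrections run here). Added after seeing the data were the libraries with most genes detected left out together, and the Y genes or the perineurial list mean as a covariate. Total counts per library lay between 19.06 and 34.18 M. The pipeline was tested on simulated counts with 200 changed genes per comparison. At a log2 change of 1, 43 of 100 genes were recovered for 7 dpi with intact, 48 for 14 dpi with intact, 38 for 14 dpi with 7 dpi and 50 for KO with WT. At a log2 change of 2 these were 54, 59, 64 and 77, and the unchanged genes called numbered 6, 4, 4 and 11. Figures were drawn with matplotlib 3.10.9. Sequence-level analysis was left out, as only gene counts were used here.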

Results

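Gene expression was profiled in endothelial cells of mouse sciatic nerve before and after injury (14 libraries) and, at 7 dpi, with and without endothelial Plxnd1, the receptor for class 3 semaphorins of vessel patterning (6 libraries). Total counts per library ran from 19.06 to 34.18 M in the Tomato experiment and from 19.25 to 33.79 M in the Cherry experiment. After the low-count filter, 20409 and 16227 genes were tested.

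Plxnd1 (chromosome 6, 115954811-115995005, GRCm38, minus strand) was measured first, since it is the deleted gene. Its level was 349, 324 and 342 CPM in the WT libraries and 131.1, 160.1 and 159.7 CPM in the KO libraries. The log2 fold change was -1.23 ± 0.10 (SE; edgeR adjusted p = 1.3e-04), or 0.427 of the WT level. Every KO library lay below every WT library, and the two-sided exact permutation p of 0.1 was the smallest that 3 against 3 allows. The change was -1.10 in batch 1133 and -1.36 in batch 1292. Counts cover the whole gene, including exons that a conditional allele may keep. The KO cells were sorted by Kdr-Cherry, and the share of them with the deletion was not measured. Cells that keep Plxnd1 may therefore be among them and dilute the KO differences. In the Tomato libraries Plxnd1 rose from 98.0 ± 36.1 CPM (SD, n = 5) in intact nerve to 264 ± 86.9 CPM (n = 5, exact permutation p = 0.00794) at 7 dpi. At 14 dpi it was at 192 ± 53.1 CPM (n = 4, exact permutation p = 0.0476 against intact). The groups at 14 and 7 dpi differed by -0.37 ± 0.17 (edgeR adjusted p = 0.229). The endothelial marker Pecam1 also averaged 1380 CPM in intact nerve and 2288 CPM at 7 dpi. A higher endothelial share of the RNA may therefore be part of the rise of Plxnd1. As the whole source it was argued against. Plxnd1 changed by 1.46 ± 0.17 (SE) at 7 dpi, while the 20 pan-endothelial genes had a median log2 fold change of 0.42.

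Endothelial cells of the lesion at 7 dpi were compared with those of intact nerve to find the genes that respond to injury. Cell division genes rose throughout: all 20 mitosis genes and all 20 DNA replication genes passed the test, with median log2 fold changes of 4.64 and 2.32. Mki67, a marker of cycling cells, rose from 3.70 ± 1.30 CPM (SD, n = 5) to 61.6 ± 10.8 CPM (n = 5). Birc5, a chromosomal passenger protein, rose by 5.34 ± 0.24 on the log2 scale (SE), and Tk1, thymidine kinase, by 4.84 ± 0.20. Both lists held with either correlation (camera adjusted p = 5.3e-39 for replication and 1.2e-84 for mitosis, and adjusted p = 0.00970 and 7.7e-04 with an estimated correlation). All 20 members of each also passed adjusted over the list alone. In all, 3202 genes rose and 3333 fell of 20409 (edgeR), 1354 and 1885 of them at least 2-fold. The fold changes of the 2 batches correlated at 0.573 over all tested genes and 0.902 over the 10306 with an average log2 CPM of at least 3, called expressed here (Pearson, across genes, which are not independent replicates). Over the called genes it was 0.920, with 1 sign in 99.9%, which calling from both batches together favours. Batch 1133 alone gave 2042 called genes (1116 up, 926 down), the Y genes as a covariate 4123 and the perineurial list mean as a covariate 760 (519 up, 241 down). Y-gene sums averaged 134 CPM in intact and 43.1 CPM in 7 dpi libraries, so the male and female makeup differed between the groups.

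Genes listed for sprouting vessels, matrix and proteases rose with them. Of 19 tip cell genes 15 rose and none fell, led by Apln, the apelin ligand (28.6 ± 2.13 CPM to 317 ± 106 CPM), and Cxcr4, a chemokine receptor (3.17 ± 0.27). The tip cell marker Esm1 rose by 1.48 ± 0.18. Adjusted over the list alone, 15 rose and 1 fell (camera adjusted p = 3.1e-13, and adjusted p = 0.0851 with an estimated correlation). Of 21 matrix genes 17 rose, including Tnc, tenascin C (3.81 ± 0.32), Col18a1 (3.20 ± 0.24) and the basement membrane collagen Col4a1 (642 ± 175 CPM to 3686 ± 1350 CPM), while Lamb2 fell (-1.45 ± 0.22). Of these genes, 18 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.4e-14, and adjusted p = 0.128 with an estimated correlation). Col4a1, Col4a2 and Nid2 are in both the tip cell and matrix lists, and Plaur is in the tip cell and protease lists. Of 18 protease genes 12 rose and 4 fell, with Mmp9 at 3.91 ± 0.60, Timp1 at 3.33 ± 0.21 and Timp3 at -1.62 ± 0.14. The counts were the same adjusted over the list alone (camera adjusted p = 3.1e-04, and adjusted p = 0.329 with an estimated correlation). Fibroblast genes, which share matrix functions, had a median of 0.98 in the same comparison, with the collagen Col1a1 at 2.49 ± 0.34. The cell source of the matrix and protease genes was not separated gene by gene. In WT Cherry libraries at 7 dpi, list means of log2(CPM + 1) were 4.93 to 5.60 for fibroblast and 8.29 to 8.34 for matrix genes. They were 6.92 to 7.35 and 6.96 to 7.61 in intact Tomato libraries. These levels argue against fibroblast RNA as the whole source of the matrix levels at 7 dpi. The experiments were normalized separately, and no intact Cherry library was available. Single genes outside these lists with steep rises were Chga, a secretory granule protein (7.46 ± 0.44), and Cd276, an immune checkpoint ligand (6.40 ± 0.26). Others were the microfibril gene Mfap4 (6.09 ± 0.65), AA467197 (5.88 ± 0.26) and the imprinted gene Mest (5.82 ± 0.26).

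Barrier genes fell. Of 20 junction and transporter genes of barrier endothelium 17 fell, with a median of -2.32. Slco1a4, an organic anion transporter, went from 850 ± 217 CPM to 19.8 ± 14.0 CPM. Slco1c1, a thyroid hormone transporter, changed by -5.15 ± 0.47 and the tight junction gene Cldn5 by -2.33 ± 0.18, while Abcc4 rose (0.85 ± 0.17). Of 16 Wnt genes 10 fell and 1 rose (median -1.92). Among the falls were the target Axin2 (-3.23 ± 0.27), the transcription factor Lef1 (56.9 ± 17.5 CPM to 7.56 ± 3.46 CPM), Foxq1 (-5.17 ± 0.41) and Tnfrsf19 (-5.22 ± 0.29). Both calls held with an estimated correlation (camera adjusted p = 1.2e-22 and 2.0e-11, and adjusted p = 0.00168 and 0.0217 with an estimated correlation). The counts were the same adjusted over the list alone. The perineurial list fell beside them, with 8 of 8 genes down both ways (median -2.64; camera adjusted p = 4.3e-08, and adjusted p = 0.182 with an estimated correlation). The claudin gene Cldn1 was at 1363 ± 363 CPM in intact nerve and at 328 ± 159.8 CPM at 7 dpi. With the perineurial mean as a covariate, the median of the 36 barrier and Wnt genes was -1.69 against -2.11 without, with 33 and 32 negative. The median SE went from 0.224 to 0.497, and 17 were called lower against 27.

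**Figure D1:**
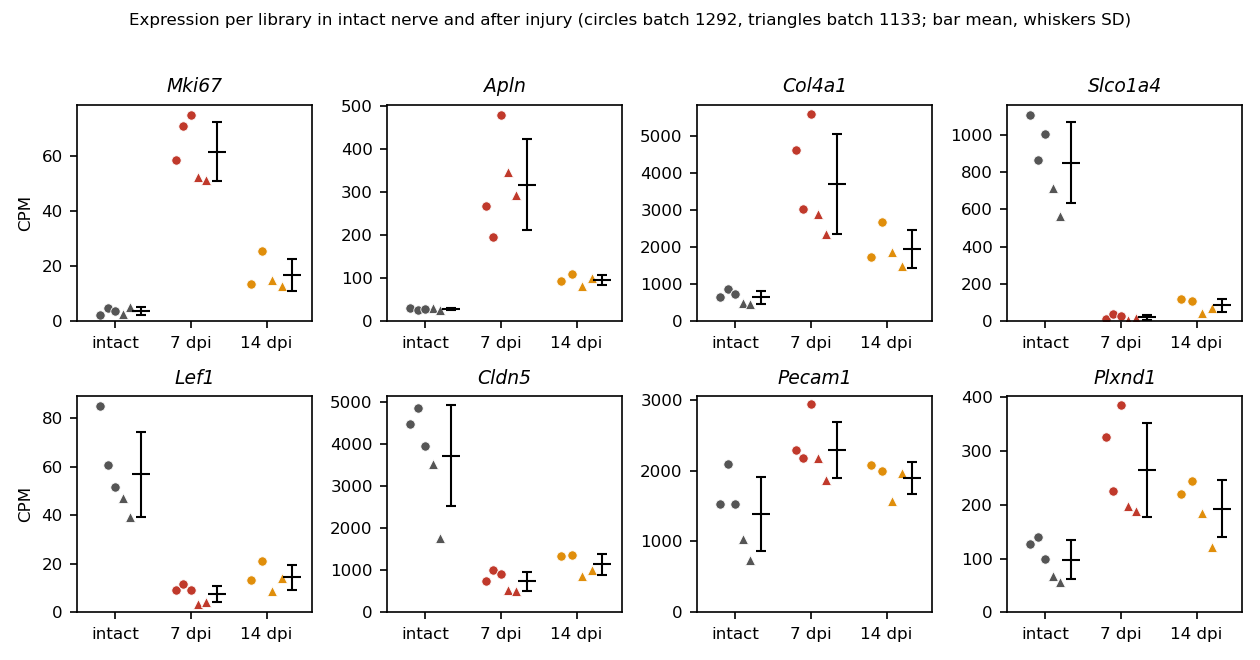
CPM of 8 genes (vertical axes, from 0) in each Tomato library, by group (horizontal axis); circles are batch 1292, triangles batch 1133, and bars and whiskers the mean and SD. Mki67 and Apln were low in intact nerve and high at 7 dpi, Slco1a4, Lef1 and Cldn5 the reverse, and Plxnd1 averaged 98.0 CPM in intact nerve, 264 at 7 dpi and 192 at 14 dpi.

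Vessel identity genes moved in both directions at 7 dpi. Pan-endothelial genes showed 10 up and 3 down of 20 (11 up and 4 down adjusted over the list alone). Pecam1 (0.78 ± 0.18), Cdh5 (0.95 ± 0.15) and Kdr (0.76 ± 0.19) rose, and Sox17 fell (-0.64 ± 0.15). A higher endothelial share of the RNA was not separated from these rises. Venous genes showed 6 up and 3 down of 11, with the apelin receptor Aplnr at 3.20 ± 0.23 and the venous transcription factor Nr2f2 at -1.61 ± 0.22. Arterial genes showed 4 up and 6 down of 15, with the kinase Bmx at -2.54 ± 0.21. Capillary genes showed 3 up and 4 down of 15, with Car4, a carbonic anhydrase, at -5.72 ± 0.37 and Gpihbp1, which anchors lipoprotein lipase, at 1.27 ± 0.18. Counts were 1 up and 5 down of 13 for Notch genes, 0 up and 5 down of 9 for lymphatic genes and 6 up and 4 down of 16 for VEGF and angiopoietin genes. They were 7 up and 5 down of 15 for flow genes, 5 up and 9 down of 21 for TGF-beta and BMP genes and 2 up and 4 down of 12 for mesenchymal transition genes. None of these 10 lists was called with the preset correlation (the lowest camera adjusted p was 0.120, for lymphatic genes). With fry, Notch (fry adjusted p = 0.0191), lymphatic (0.0383) and arterial genes (0.0412) were called lower. YAP and TAZ targets showed 0 up and 6 down of 16, with the receptor kinase Axl at -1.33 ± 0.22, and at 0.10 with the perineurial covariate (camera adjusted p = 0.0461, and adjusted p = 0.531 with an estimated correlation; 0 up and 6 down adjusted over the list alone). Among guidance genes, the semaphorin family showed 4 up and 13 down of 30 (camera adjusted p = 0.134), with Sema3b at -2.99 ± 0.32 and Sema3d at -2.03 ± 0.30 (0.14 with the perineurial covariate). The other guidance genes showed 3 up and 9 down of 24 (camera adjusted p = 0.313). Both guidance lists were called lower with fry (fry adjusted p = 0.0376 for the semaphorin family and 0.0126 for the other genes). Median and mean differed in sign for the capillary, TGF-beta, mesenchymal transition and angiocrine lists.

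Genes for leukocyte capture rose at 7 dpi while interferon and immediate early genes fell. Of 17 adhesion and chemokine genes 12 rose and 2 fell, counts that were the same adjusted over the list alone (camera adjusted p = 5.4e-04, and adjusted p = 0.531 with an estimated correlation). E-selectin (Sele) went from 40.4 ± 30.1 CPM to 301 ± 61.5 CPM, with Icam1 at 1.35 ± 0.20, Madcam1 at 4.58 ± 0.56 and the lipocalin Lcn2 at -4.58 ± 0.30. Of 20 interferon genes 12 fell both ways and none rose, including Ifit1 (-2.25 ± 0.25) and Ifit3 (-2.40 ± 0.26). The list had a camera adjusted p = 7.8e-05, and adjusted p = 0.531 with an estimated correlation. Of 15 immediate early genes, which also respond to dissociation, 11 fell both ways and none rose, including Egr1 (-1.24 ± 0.20). This list had a camera adjusted p = 8.0e-04, and adjusted p = 0.543 with an estimated correlation. Antigen presentation genes showed 0 up and 7 down of 14 (camera adjusted p = 0.0961, fry adjusted p = 0.0343; 0 up and 9 down adjusted over the list alone).

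Marker genes of other nerve cells were detected in the Tomato libraries, although the cells were sorted as reporter-positive and CD45-negative. Carried-over RNA and expression in the sorted cells were not separated. Fibroblast genes showed 8 up and 3 down of 17 (10 up and 3 down adjusted over the list alone; camera adjusted p = 0.0482, and adjusted p = 0.696 with an estimated correlation). Col1a1 was at 2.49 ± 0.34 and decorin (Dcn) went from 9687 ± 3139 CPM to 3560 ± 1744 CPM. Mural genes showed 0 up and 7 down of 13 (camera adjusted p = 0.00415, and adjusted p = 0.531 with an estimated correlation), with Cspg4 at -2.10 ± 0.23. Schwann genes showed 1 up and 7 down of 14 (camera adjusted p = 0.00882, and adjusted p = 0.531 with an estimated correlation), with the myelin gene Mbp at -4.57 ± 0.44. Red cell genes showed 0 up and 5 down of 5 (camera adjusted p = 0.0158, and adjusted p = 0.531 with an estimated correlation). Macrophage genes showed 2 up and 0 down of 14 (camera adjusted p = 0.168), other leukocyte genes 0 up and 1 down of 4 (0.526) and muscle and fat genes 0 up and 2 down of 8 (0.268). The last 2 lists were called lower with fry (fry adjusted p = 0.00421 and 0.0294). Ctss, a macrophage protease, rose by 6.18 ± 1.62, a call that ended without intact replicate 4 (5.59, edgeR adjusted p = 0.0541). The library 7 dpi replicate 4 held 244 CPM of the macrophage gene Lyz2. In the Cherry libraries, normalized separately, Dcn was at 34.1 to 199 CPM and Cldn1 at 0.492 to 6.03 CPM. With the perineurial covariate, Cldn1 (0.38) and Dcn (1.09) had positive values at 7 dpi.

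**Figure D2:**
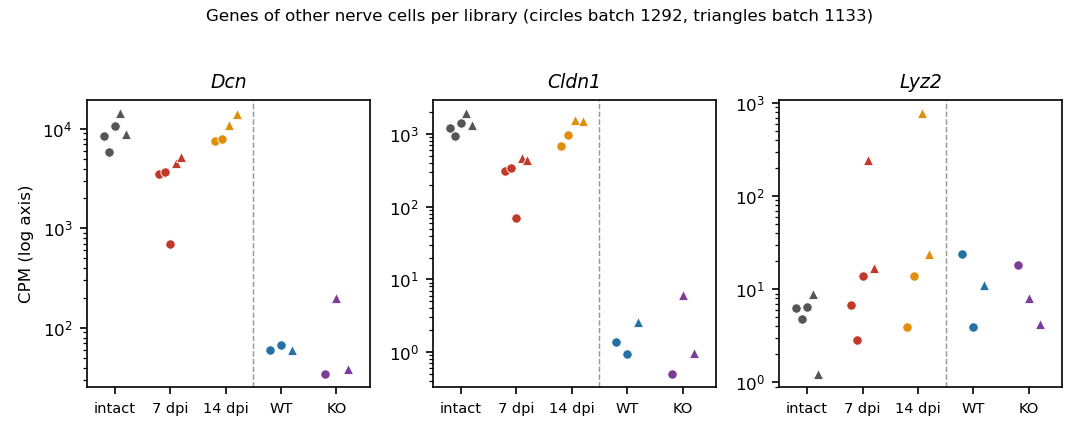
CPM (log axis) of Dcn, Cldn1 and Lyz2, genes of fibroblasts, perineurial cells and macrophages, in each library by group (horizontal axis); circles are batch 1292, triangles batch 1133, and the dashed line parts the Tomato and Cherry tables, which were normalized separately. Dcn ran from 702 to 14330 CPM in Tomato libraries, and Lyz2 reached 777 CPM in 14 dpi replicate 3.

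At 14 dpi the cells were again compared with intact nerve (n = 4 and 5). All 20 mitosis genes were still higher, with a median of 2.55 (camera adjusted p = 2.1e-68, and adjusted p = 0.00123 with an estimated correlation). Cdk1 was at 3.25 ± 0.18, and Mki67 at 16.7 ± 5.90 CPM (SD, n = 4). Of the replication genes 16 of 20 rose (18 adjusted over the list alone; camera adjusted p = 6.7e-18, and adjusted p = 0.0718 with an estimated correlation). Barrier genes remained low, with 16 of 20 down (17 adjusted over the list alone; median -1.28), including Slco1a4 at 84.6 ± 34.3 CPM, Slco1c1 (-4.61 ± 0.49) and Cldn5 (-1.61 ± 0.19). Of 16 Wnt genes 7 fell (10 adjusted over the list alone), including Lef1 (-1.89 ± 0.22). The perineurial list moved with them, with 0 up and 4 down of 8 and a median of -1.25. The barrier and Wnt lists held (camera adjusted p = 1.1e-23 and 7.3e-12, and adjusted p = 0.00123 and 0.0187 with an estimated correlation). Matrix genes showed 16 up and 0 down of 21 (17 up and 0 down adjusted over the list alone; camera adjusted p = 1.1e-19, and adjusted p = 0.0766 with an estimated correlation). Their median was 1.22 beside 2.00 for fibroblast genes, and the cell source was not separated. Lamb1 was at 2.64 ± 0.29 and Col15a1 at 2.44 ± 0.29. Tip cell genes showed 11 up and 2 down of 19 (11 up and 2 down adjusted over the list alone; camera adjusted p = 1.8e-06, and adjusted p = 0.255 with an estimated correlation). Apln was at 1.76 ± 0.20, while Esm1 did not pass (-0.40 ± 0.19). Among single genes, Plac8 rose by 4.72 ± 0.52, Chga by 5.27 ± 0.42 and Mfap4 by 5.80 ± 0.66. Zbtb16, a zinc finger transcription factor (-3.78 ± 0.65), Lcn2 (-3.51 ± 0.31), Thsd4 (-3.35 ± 0.36) and Cytl1 (-3.30 ± 0.47) fell. In all, 1401 genes rose and 1038 fell (edgeR). The fold changes of the 2 batches correlated at -0.156 over all tested genes and 0.706 over expressed ones (Pearson), and the called genes, chosen from both batches, all had 1 sign. Batch 1133 alone gave 795 called genes (616 up, 179 down), batch 1292 alone 1500 (719 up, 781 down) and the perineurial covariate 1231 (850 up, 381 down). Falls also outnumbered rises with library size as the only scaling (1418 up, 1497 down) and with the 2 groups alone (1141 up, 1205 down).

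Fibroblast genes were higher at 14 dpi than in intact nerve, with 11 up and 0 down of 17 both ways and a median of 2.00 (camera adjusted p = 1.3e-14, and adjusted p = 0.104 with an estimated correlation). Lum, lumican, was at 3.08 ± 0.45 and Col1a1 at 5872 ± 2563 CPM. Proteases showed 9 up and 1 down of 18 (camera adjusted p = 1.3e-04, and adjusted p = 0.255 with an estimated correlation), with the gelatinase Mmp2 at 3.20 ± 0.38. Adhesion genes showed 10 up and 2 down of 17 (camera adjusted p = 2.8e-05, and adjusted p = 0.292 with an estimated correlation), with the chemokine Ccl2 at 2.77 ± 0.29 and Sele at 2.46 ± 0.39. Capillary genes showed 6 up and 1 down of 15 (camera adjusted p = 7.7e-04, and adjusted p = 0.292 with an estimated correlation). The fatty acid binding genes Fabp5 and Fabp4 were at 2.00 ± 0.24 and 1.09 ± 0.24, and Car4 at -2.69 ± 0.35. Other lists called with the preset correlation, none of them with an estimated one, were interferon (0 up and 5 down of 20, adjusted p = 0.387 with an estimated correlation), perineurial (0 up and 4 down of 8, 0.292) and mural genes (0 up and 2 down of 13, 0.534). The same held for lymphatic (0 up and 3 down of 9, 0.292), YAP and TAZ (0 up and 3 down of 16, 0.141) and hypoxia genes (2 up and 7 down of 22, 0.349). It held as well for Schwann (5 up and 1 down of 14, 0.387) and macrophage genes (5 up and 0 down of 14, 0.534). Kdr (0.41 ± 0.20), Pecam1 (0.56 ± 0.19) and Cldn1 (-0.34 ± 0.32) did not pass, but Pecam1 did without intact replicate 2 (0.68). The macrophage protease gene Ctss rose by 7.53 ± 1.62, with a mean of 49.2 ± 92.8 CPM (SD, n = 4). Macrophage markers, which the CD45-negative sort should deplete, were highest in 14 dpi replicate 3, which held 36.6 CPM of the complement gene C1qa against 1.09 CPM or less in the other 14 dpi libraries and 7.71 CPM in 7 dpi replicate 4. Median and mean differed in sign for other guidance, TGF-beta and other leukocyte genes at 14 dpi, none of them called.

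**Figure D3:**
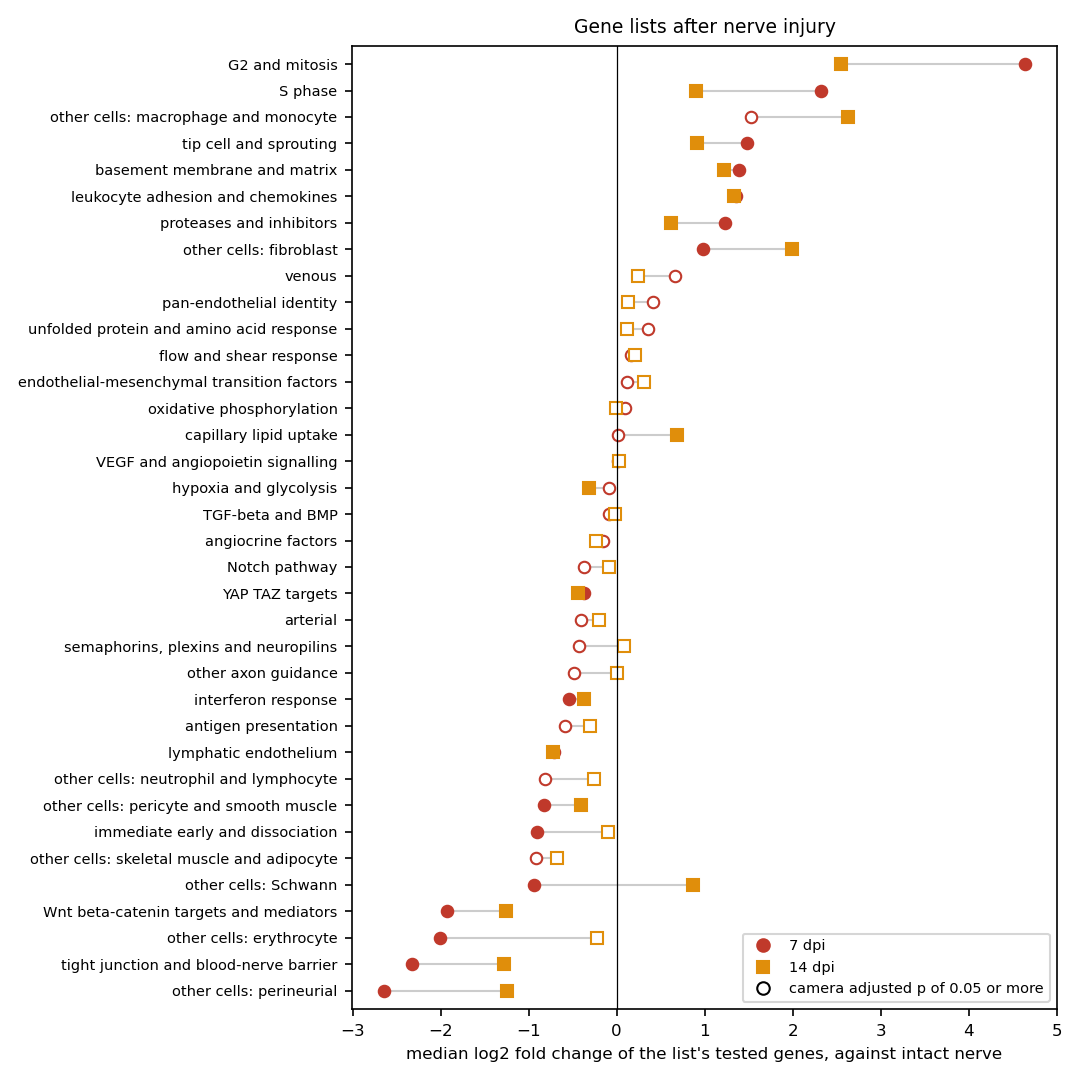
Median log2 fold change against intact nerve (horizontal axis) of the tested genes of each of the 36 lists (vertical axis) at 7 dpi (circles) and 14 dpi (squares); open marks are lists with a camera adjusted p of 0.05 or more at the preset correlation. The mitosis list stood at 4.64 and 2.55, the barrier list at -2.32 and -1.28, and the Schwann list at -0.94 and 0.87.

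The later injured group was then compared with the earlier one (14 dpi, n = 4, with 7 dpi, n = 5). Mitosis and replication genes were lower at 14 dpi, 20 of 20 and 18 of 20 (20 of each adjusted over the list alone), with Plk1, a mitotic kinase, at -2.44 ± 0.26, Birc5 at -2.48 ± 0.23 and Mcm5 at -1.93 ± 0.19. Barrier genes were higher on balance, with 11 up and 1 down of 20 (13 up and 1 down adjusted over the list alone). The rises included Mfsd2a, a lipid transporter (2.31 ± 0.44), Slco1a4 (2.24 ± 0.33) and Cldn5 (0.71 ± 0.18). The perineurial list rose beside them (median 1.17), and with its mean as a covariate Slco1a4 was at 2.31 and passed, while Mfsd2a (2.86) and Cldn5 (0.66) did not. These calls held with an estimated correlation (camera adjusted p = 1.5e-69, 4.1e-41 and 2.2e-09, and adjusted p = 0.00319, 0.00684 and 0.0221 with an estimated correlation). Wnt genes showed 7 up and 0 down of 16 (9 up and 0 down adjusted over the list alone; camera adjusted p = 1.6e-05, and adjusted p = 0.0882 with an estimated correlation). Tnfrsf19 was at 2.23 ± 0.28 and Nkd1 at 1.56 ± 0.23. Capillary genes showed 9 up and 0 down of 15 both ways (camera adjusted p = 1.5e-05, and adjusted p = 0.219 with an estimated correlation), with Car4 at 3.04 ± 0.34. Tip cell genes showed 0 up and 10 down of 19 (0 up and 11 down adjusted over the list alone; camera adjusted p = 1.9e-12, and adjusted p = 0.0882 with an estimated correlation). Esm1 was at -1.88 ± 0.20 and Apln at -1.71 ± 0.20. Mest (-2.66 ± 0.24), Nts, neurotensin (-2.82 ± 0.58), and Crmp1 (-3.08 ± 0.32) fell steeply.

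Schwann cell marker genes differed between the injured groups. The myelin genes Mbp (4.96 ± 0.45) and Ncmap (3.70 ± 0.41) rose. The list showed 7 up and 0 down of 14 (10 up and 0 down adjusted over the list alone; camera adjusted p = 5.0e-15, and adjusted p = 0.0326 with an estimated correlation). Myocilin (Myoc; 3.74 ± 0.51) and Ptgds, a prostaglandin D synthase (4.28 ± 0.41), also rose. Fibroblast genes showed 7 up and 1 down of 17 (camera adjusted p = 3.5e-07, and adjusted p = 0.285 with an estimated correlation). Perineurial genes showed 5 up and 0 down of 8 (camera adjusted p = 2.4e-07, and adjusted p = 0.204 with an estimated correlation), with the Wnt ligand Wnt6 at 1.99 ± 0.35. Red cell genes showed 5 up and 0 down of 5 (camera adjusted p = 3.6e-05, and adjusted p = 0.219 with an estimated correlation). Immediate early genes showed 7 up and 0 down of 15 (12 up and 0 down adjusted over the list alone; camera adjusted p = 1.5e-07, and adjusted p = 0.281 with an estimated correlation), with Egr1 at 1.21 ± 0.22. The semaphorin family showed 7 up and 1 down of 30 (9 up and 1 down adjusted over the list alone; camera adjusted p = 0.00237, and adjusted p = 0.511 with an estimated correlation), with Sema5a at 2.22 ± 0.22. Lists also called with the preset correlation alone were pan-endothelial (1 up and 0 down of 20, adjusted p = 0.694 with an estimated correlation) and matrix genes (1 up and 4 down of 21, 0.641). The pan-endothelial list was called lower at 14 dpi, with a median of -0.27 and 15 of 20 values negative. Hypoxia (2 up and 6 down of 22, 0.641), interferon (3 up and 0 down of 20, 0.694) and mural genes (2 up and 0 down of 13, 0.675) were called in the same way. VEGF and angiocrine genes, not called, had a median and a test or mean of opposite sign. In all, 1170 genes rose and 857 fell (edgeR). The fold changes of the 2 batches correlated at -0.00781 over all tested genes and 0.804 over expressed ones (Pearson), and the called genes, chosen from both batches, all had 1 sign. The count was 1305 without 14 dpi replicate 2, 1226 without a batch term and 3255 with DESeq2. It was 366 (264 up, 102 down) in batch 1133 alone and 726 (249 up, 477 down) in batch 1292 alone. With the perineurial covariate it was 170 (59 up, 111 down).

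The responses at 7 and 14 dpi were compared, with the intact libraries shared between them. Their fold changes correlated at 0.730 (Pearson) and 0.694 (Spearman) across 20409 genes, against 0.108 and 0.0413 for simulated unchanged groups, with a covariance of 0.661 against 0.0276. Genes called up in both numbered 1205 and down in both 976, where independent lists would give 219.8 and 169.5, and 10 were called in opposite directions. With the intact libraries split between the comparisons, the median Pearson correlation over 20 splits was 0.358 (0.125 to 0.532), the covariance 0.447, and the shared calls 724.5 up and 600.5 down, with 9.5 in opposite directions. The covariance dropped by more than the simulated value, so the simulated value may understate what the shared libraries bring. No gene passed a test of a batch difference in the injury response (edgeR, 1973 of 20409 at an unadjusted p under 0.05), and without the low-count filter 452 of 50031 did. Tested alone, the 7 dpi response had 945 genes at an unadjusted p under 0.05 and the 14 dpi response 3287. The counts of 1973 and 3287 exceed what chance gives on average at that threshold. The lack of calls therefore does not show that the batches responded alike.

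Deletion of Plxnd1 was examined at 7 dpi by comparing KO with WT bridge endothelial cells (n = 3 and 3). Few genes changed: 21 rose and 29, Plxnd1 among them, fell of 16227 (edgeR), with 16 and 36 under library-size scaling. Interferon genes were higher, with 6 of 20 up and none down, including Ifit3 (1.16 ± 0.16) and Oas1a (0.99 ± 0.13). The interferon-induced genes Oasl1 (1.46 ± 0.22), Zbp1 (1.37 ± 0.20) and Ifi27l2a (1.40 ± 0.17) also rose, and 14 of the list rose and 1 fell adjusted over the list alone (camera adjusted p = 8.5e-24, and adjusted p = 0.249 with an estimated correlation). Leukocyte adhesion genes were lower, 5 of 17 and 9 adjusted over the list alone (camera adjusted p = 1.3e-07, and adjusted p = 0.304 with an estimated correlation). They included Sele (468 ± 85.8 CPM to 308 ± 28.5 CPM, SD, n = 3), Selp (-0.56 ± 0.09), Icam1 (-0.65 ± 0.11) and Tnfaip3 (-0.89 ± 0.15). Immediate early genes showed 0 up and 2 down of 15 (0 up and 12 down adjusted over the list alone; camera adjusted p = 8.2e-16, and adjusted p = 0.265 with an estimated correlation). Fosb was at -0.76 ± 0.10 and Nr4a1 at -0.80 ± 0.11, and the related receptor gene Nr4a2 (-1.05 ± 0.15) and Tacr1, the substance P receptor (-1.03 ± 0.13), also fell. Apln rose (0.92 ± 0.16), and Pecam1 (0.10 ± 0.09), Cdh5 (0.31 ± 0.10) and Kdr (-0.10 ± 0.09) did not pass. The genotypes did not overlap in Xist (158.5 to 374 CPM in WT, 85.8 to 134 CPM in KO). Nor did they overlap in Y-gene sums (73.4 to 78.2 CPM in WT, 80.0 to 107 CPM in KO). The male and female makeup was therefore not separated from genotype in the interferon, adhesion and immediate early differences. The fold changes of the 2 batches correlated at 0.0646 over all tested genes and 0.339 over the 9590 expressed ones (Pearson). All 50 called genes had 1 sign in both batches, which calling from both batches together favours. The count was 25, 40 and 11 without WT replicates 1, 2 and 3, and 9, 39 and 6 without KO replicates 1, 2 and 3. It was 5 without a batch term, 241 with DESeq2, 230 without the filter and 550 on the authors' batch-corrected counts.

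Genes next to Plxnd1 and a gene on another chromosome had the steepest rises in the KO libraries. Mbd4, a DNA glycosylase (chromosome 6, 115840697-115853371), rose from 21.6 ± 5.13 CPM to 155 ± 10.8 CPM (SD, n = 3) and its neighbour Ift122, an intraflagellar transport gene (chromosome 6, 115853470-115926699), from 46.0 ± 3.97 CPM to 284 ± 46.2 CPM. The spans of Mbd4 and Ift122 do not overlap in these coordinates. The strand setting of the counting is not stated. Reads of transcripts that run past a gene's end may therefore be counted for a neighbour on the opposite strand. Also within 1 Mb, Tmcc1 (1.01 ± 0.13) and Timp4 (1.26 ± 0.23) rose. Esr1, the estrogen receptor gene (chromosome 10, 4611989-5005614), rose by 5.17 ± 0.23. Moxd1 fell (-1.61 ± 0.13), as did Clca3a2 (-1.25 ± 0.20) and Tmem87a (-1.03 ± 0.15). Esr1, Mbd4, Ift122, Moxd1 and Plxnd1 were the called genes named here that passed with each library left out; the other calls ended in at least 1 of those fits.

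**Figure D4:**
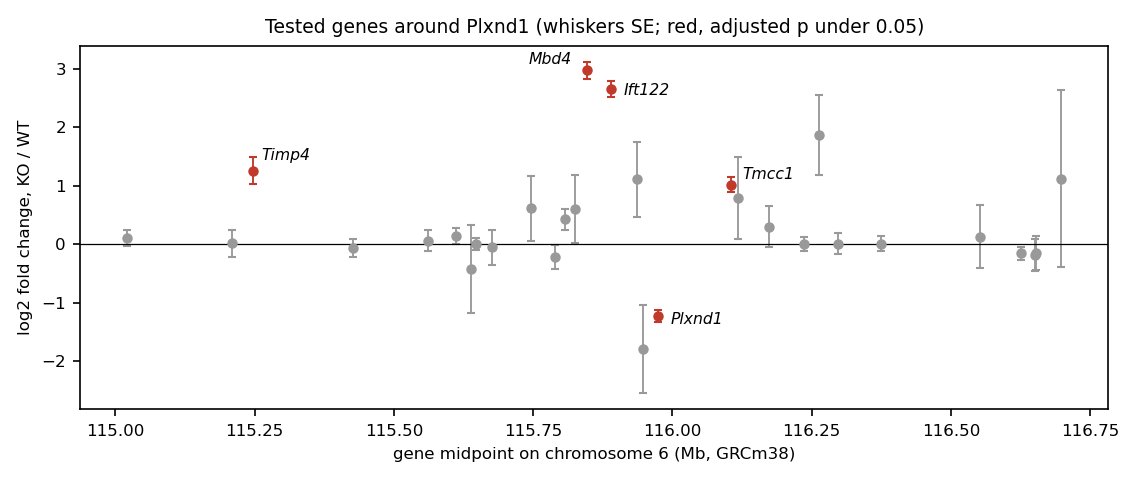
Log2 fold change of KO over WT (vertical axis; whiskers, SE) of the tested genes within 1 Mb of Plxnd1, by position on chromosome 6 (horizontal axis, Mb); red points have an adjusted p under 0.05. Mbd4 (2.97) and Ift122 (2.65) lie beside Plxnd1 (-1.23).

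No list was called in the KO comparison with an estimated correlation or with fry, and 14 were with the preset one, 6 of them up and 8 down. Each was called at the preset correlation alone, with the estimated adjusted p given here. The semaphorin family list includes the deleted gene. It showed 0 up and 1 down of 29 and 0 up and 3 down adjusted over the list alone (adjusted p = 0.249 with an estimated correlation). The 1 called fall was Plxnd1 itself, which the genotype fixes, and the list was not tested without it. Plxna4 (-0.93 ± 0.19) and Sema4c (-0.51 ± 0.13) passed beside Plxnd1 over the list alone. Replication genes showed 0 up and 0 down of 20, 7 up and 0 down adjusted over the list alone (adjusted p = 0.307 with an estimated correlation), and mitosis genes 0 up and 0 down of 20 (0.304). Respiratory chain genes showed 0 up and 0 down of 22, 8 up and 0 down adjusted over the list alone (adjusted p = 0.265 with an estimated correlation). Tip cell genes showed 1 up and 0 down of 19 (0.304), venous genes 0 up and 2 down of 11 (0.249) and antigen presentation genes 0 up and 0 down of 14 (0.304). The 2 venous genes were Selp and Icam1, which are also in the adhesion list, as are the venous genes Vcam1, Ackr1 and Lcn2. The venous call is therefore not separate from the adhesion call. Wnt genes showed 0 up and 0 down of 12 (0.304), YAP and TAZ targets 0 up and 0 down of 15 (0.304) and perineurial genes 0 up and 1 down of 5 (0.249). As list means of log2(CPM + 1), Wnt genes averaged 2.58 in WT and 2.46 in KO libraries, and YAP and TAZ targets 5.13 and 5.05. Mitosis genes averaged 6.02 in WT and 6.09 in KO libraries, and antigen presentation genes 5.20 and 5.36. Schwann genes had a median of -1.59, with 0 up and 0 down of 14 and 0 up and 3 down adjusted over the list alone (adjusted p = 0.304 with an estimated correlation). Median and test differed in sign for the capillary and red cell lists, and mean and test for the protease and fibroblast lists, none of them called.

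Injury-responsive genes were followed into the KO comparison, which shares no libraries with the time course. Genes raised at least 2-fold at 7 dpi (1317 tested) had a median log2 fold change of 0.10 in KO over WT, and genes lowered (1432 tested) one of -0.15 (camera adjusted p = 0.00134 and 0.00572, and adjusted p = 0.236 with an estimated correlation for each). Across 16055 genes the fold changes of injury and of deletion correlated at 0.110 (Pearson) and 0.178 (Spearman), as a description over genes. Of 49 genes called in the KO comparison and tested in the time course, 37 were also called at 7 dpi, where 6041 of the 16055 genes tested in both were called. Of these 37, 7 were raised in both, as Apln was, and 5 lowered in both. The others were 15 raised by injury and lower in KO, as Sele, Icam1 and Plxnd1 were, and 10 lowered by injury and higher in KO, as Ifit3 was.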

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

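The tests of the endothelial share, of the Plxnd1 region, of Esr1 reads and of fibroblast RNA were chosen only after the result was seen, and the 2 covariate tests were chosen after the data were seen, with their bounds set before they were run. In 129 groups of 4 or 5 values, 10 held a library far from the rest of its group by Dixon's criterion, where chance gives about 1 in 20. The TMM factor of intact replicate 5 was 1.32 (others 0.937 to 0.998). As means of log2(CPM + 1) over a list, the macrophage value was 5.00 (others 1.16 to 1.72) in 14 dpi replicate 3 and 3.32 (others 1.04 to 1.61) in 7 dpi replicate 4. The library 14 dpi replicate 3 also had an antigen presentation value of 6.26 (others 5.30 to 5.35) and an other-leukocyte value of 0.761 (others 0.349 to 0.374). The perineurial value was 4.67 (others 6.43 to 6.80) in 7 dpi replicate 3 and the lymphatic value 4.92 (others 4.18 to 4.39) in 7 dpi replicate 2. The angiocrine value was 4.19 (others 4.31 to 4.35) in 7 dpi replicate 4, the barrier value 6.19 (others 5.99 to 6.01) in 14 dpi replicate 2, and the unfolded protein value 6.58 (others 6.38 to 6.41) in 14 dpi replicate 4. The injury responses at 14 and 7 dpi differed in 2027 genes by the test of the difference itself.

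The real grouping of the libraries was set against other groupings of the same libraries. Of 50 groupings, 1, the real one, gave as many called genes for 7 dpi with intact (6535, highest other 0), for 14 dpi with intact (2439, highest other 1091) and for 14 dpi with 7 dpi (2027, highest other 412), which argues against chance as the source of these counts. The KO comparison has 10 groupings, too few for a share under 0.05; the real one gave 50 genes and the highest of the other groupings 0, with 1 of 10 as large.

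Barrier and Wnt genes (36 genes; Slco1a4, Cldn5, Lef1 and others) were lower at 7 dpi, with a median log2 fold change of -2.11 (95% bootstrap interval -2.79 to -1.49). The intervals given here resample the genes of the list, which are not independent, and do not measure the spread between libraries. Less perineurial RNA in the injured libraries was argued against only weakly as the whole source. With the perineurial mean as a covariate, which took the changed genes to 760, the median was -1.69 (-2.37 to -1.38). With it, 17 genes were called lower against 27, as the median SE went from 0.224 to 0.497. The perineurial means did not overlap between the groups (7.97 to 9.30 in intact, 4.675 to 6.80 at 7 dpi), so this fit extends trends seen within groups. A lower endothelial share was argued against by the pan-endothelial list, whose median was 0.42. With the Y-gene covariate the median was -1.84 and 26 genes were called lower, which argues only weakly against the male and female makeup. Intact libraries all held Y-gene reads (40.1 to 239 CPM), while at 7 dpi replicate 1 held 215 CPM and the others at most 0.029 CPM. What stays open is a response of endothelial cells to injury, and a difference between the whole nerve and the bridge, which the design does not separate. The male and female makeup and less perineurial RNA stay open in part. An injury response may underlie the fall, as a hypothesis found on these data and not itself tested.

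Esr1 and the genes beside Plxnd1 were higher in KO libraries. Among 29 tested genes within 1 Mb of Plxnd1, 4 were called, but the window was set around genes already seen to be called, so the count does not decide whether DNA was changed or carried along at the locus, and linked variants and transcription across the edited allele stay open. For Esr1, 14 of 14 Tomato libraries (33.9 to 90.1 CPM), whose mice carry CreERT2, lay above the highest WT Cherry library (3.67 CPM), as the KO libraries did (96.3 to 108 CPM), so reads of the transgene's receptor domain are a candidate source. The design text writes CreER for the Plxnd1 mice, no label says whether the WT mice carry it, and Tomato libraries also held more Dcn (702 to 14330 CPM, against at most 67.0 in WT), so Esr1 RNA of other cells is not excluded there. Fibroblast RNA in the KO libraries was argued against by the fibroblast list, with a median of -0.075. For Esr1, levels seen afterwards argue against the male and female makeup. WT libraries held Y-gene (73.4 to 78.2 CPM) and Xist reads (158.5 to 374 CPM) with little Esr1, and the KO Y-gene sums were 80.0 to 107 CPM. An effect of Plxnd1 loss itself and, for the genes beside Plxnd1, the male and female makeup, untested here, stay open.

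The authors' batch-corrected Cherry counts gave 550 called genes with genotype alone in the model, against 50 from uncorrected counts with batch in the model. A correction that protects genotype, followed by a test that does not count the batch term, could raise calls by its construction, and the test corrected the other groupings in the same way. Over 8 other groupings the median of called genes was 0 after correction and 0 before, so the ratio set in advance is undefined and the test does not decide, although the bound set against this explanation was met in the letter. In 2 of the 8 groupings correction gave more calls, up to 176, and the real grouping went from 50 to 705 when corrected here. Without a batch term, the grouping that follows batch called 1076 genes and the real one 5, which points to a batch structure in these libraries; that grouping could not be fitted with batch, and the real one with batch gave 50.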

How the results depend on the processing

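The perineurial and Y-gene covariates and the joint removal of intact replicate 5 and 7 dpi replicate 5 were chosen only after the data were seen. For 7 dpi with intact, DESeq2, both other scalings, both other filters, no batch term, the 2 groups alone, batch 1292 alone and the title-number blocks gave 4973 to 7610 called genes; batch 1133 alone gave 2042, the Y covariate 4123 and the perineurial covariate 760. For 14 dpi with intact the count was 795 and 1500 in batches 1133 and 1292 alone and 1231 with the perineurial covariate. For 14 dpi with 7 dpi it was 3255 with DESeq2, 1226 without batch, 366 and 726 in the batches alone and 170 with the perineurial covariate. For KO with WT it was 241 with DESeq2, 230 without the filter, 5 without batch and 550 on ComBat-Seq counts, 52 with library size (16 up, 36 down), and 47 with limma voom. The single-batch counts rest on fewer libraries, and the perineurial mean itself differs between the groups; otherwise the cause was not tested. With each library left out, the counts ran from 5808 to 6805, from 1784 to 2617, from 1305 (without 14 dpi replicate 2) to 2656, and from 6 (without KO replicate 3) to 40, and leaving out WT replicate 3 or KO replicate 1 left a batch without 1 of the groups. Without intact replicate 5 and 7 dpi replicate 5 they were 6429, 2555 and 2162.

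The perineurial covariate turned the sign of Cldn1 (0.38), Axl (0.10), Sema3d (0.14), Dcn (1.09) at 7 dpi and of Cldn1 (0.83) at 14 dpi; each had fallen or, for Cldn1 at 14 dpi, not passed, and the cause was not tested beyond the covariate's own construction. No other alternative turned a named gene. Of 61, 32, 22 and 28 genes named for the 4 comparisons in turn, 34, 26, 16 and 7 kept their direction and call under every alternative, and 60, 31, 22 and 10 with each library left out. These numbers include genes that were not called and stayed so. In the KO comparison the called genes kept with each library left out were Esr1, Mbd4, Ift122, Moxd1 and Plxnd1. Lists called with an estimated correlation numbered 4, 3, 4 and 0 in the 4 comparisons (16, 18, 17 and 14 with the preset one), and with fry 23, 17, 13 and 0; the KO medians of the injury genes, 0.10 and -0.15, lost their call with an estimated correlation (adjusted p = 0.236). Splitting the intact libraries took the correlation of the 7 and 14 dpi responses from 0.730 to 0.358, with fewer and unshared controls, and dropping the filter took the batch difference from 0 to 452 genes. Plxnd1 stayed at -1.17 to -1.29 in KO over WT.

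Replicate numbers here only name libraries. Blocks of libraries with neighbouring title numbers gave 6265, 2049 and 1641 called genes in the time course; within such a set the libraries' deviations correlated at a median of -0.066, and 1 of 14 libraries correlated best with its own set. At the depths here, simulations recovered 38 to 50 of 100 genes changed 2-fold and 54 to 77 of 100 changed 4-fold.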

Other observations

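The window on chromosome 10 and the levels set across experiments were looked at only after the result was seen. Metabolic genes split at 7 dpi. Of 22 hypoxia and glycolysis genes 7 rose and 9 fell (camera adjusted p = 0.384; 7 up and 9 down adjusted over the list alone), with lactate dehydrogenase Ldha at 1.11 ± 0.16 and carbonic anhydrase Car9 at 4.23 ± 0.58 (edgeR, SE). The glucose transporter Slc2a1, also in the barrier list, went from 2506 ± 303 CPM to 384 ± 83.2 CPM (SD, n = 5 each) and Ndrg1 was at -1.88 ± 0.17. Respiratory chain genes showed 3 up and 1 down of 22 (0.358; 2 up and 0 down adjusted over the list alone). Stress and amino acid genes showed 8 up and 5 down of 17 (0.268; 9 up and 6 down adjusted over the list alone), with the serine synthesis gene Psat1 at 1.73 ± 0.18, asparagine synthetase Asns at 1.40 ± 0.19 and the glutathione-degrading enzyme gene Chac1 at -2.26 ± 0.34.

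Secreted factors also went both ways: of 25 angiocrine genes 7 rose and 8 fell at 7 dpi (camera adjusted p = 0.820; 8 up and 10 down adjusted over the list alone), with the growth factor Igf1 at 2.62 ± 0.19 and Bmp6 at -2.51 ± 0.24. At 14 dpi Edn1, endothelin 1, was lower than in intact nerve (-1.89 ± 0.22) and the BMP modulator Bmper higher (2.97 ± 0.40).

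Intact libraries of batch 1133 had Y-gene sums of 163 and 117 CPM and Xist at 0.781 and 1.33 CPM, while the injured libraries of that batch had Y-gene sums of 0 to 0.0290 CPM and Xist at 149 to 240.1 CPM. In batch 1292, intact and 14 dpi libraries held Y-gene reads in each case, some with Xist as well, and 7 dpi libraries held 1 or the other. All 6 Cherry libraries held both Y-gene and Xist reads, and the genotypes did not overlap in either. Xist was at 158 to 374 CPM in WT and 85.8 to 134 CPM in KO, and the Y-gene sums were 73.4 to 78.2 CPM in WT and 80.0 to 107 CPM in KO. No covariate for them was fitted in the KO comparison.

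In the KO comparison, 5 called genes (Esr1, Tnfaip3, Mtfr2, Raet1e and Moxd1) lay within 20 Mb on chromosome 10, and 49 of 1000 random draws of as many genes had a window with as many. Moxd1, which is in the perineurial list, was at 49.3 to 207 CPM in Cherry libraries, where Cldn1 of that list was at 6.03 CPM or less.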
